A study of Mus musculus and Homo sapiens with 29 samples.

How the data were processed

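The series held 29 samples: 13 RNA-seq libraries (4 from MCF-7, 9 from B16) and 16 ChIP-seq libraries, 4 of them inputs. Per the labels, MCF-7 cells were transduced with lentiviral short hairpin RNA and selected for 6 to 8 days. B16 cells carried a fluorescent label, were injected under the skin of C57BL/6 mice, and were recovered after 14 days by collagenase digestion and sorting for the label. The groups were MCF-7 control and LSD1 knockdown (2 RNA libraries each), and B16 scramble, LSD1 knockout and LSD1/MDA5 double knockout (3 RNA libraries each). Columns were assigned to groups only from the deposited column names and the labels.

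The authors deposited raw counts per gene for each RNA library, as whole numbers with no normalization, and the column names are those of STAR's gene counting. They also deposited expected counts per repeat family, in steps of 0.5 and with no normalization. How reads at several sites were counted, the annotation release and the strand setting are not given in the sources used here. For each ChIP library but the inputs the authors deposited a peak list (12 in all) with the fold enrichment of each peak over the caller's background, its −log10 p-value and −log10 q-value, and a score that is 10 times the −log10 q-value rounded down in at least 99.97% of the peaks of each list. The lists also hold a summit offset. The submitters' processing notes list BWA 0.7.2-r351, SAMtools 0.1.18, MACS2 2.0.10.20131216, STAR 2.4.2a, edgeR 3.18.1 and HOMER with no version, with genome builds hg19 and mm9. Which control each peak call used, and its settings, are not given in the sources used here. Input libraries had no peak list and are not analysed here. Peak calling per library means that the number of peaks follows depth and enrichment as well as occupancy, and the read depth of the ChIP libraries is not given in the sources used here.

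Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM factors, the filterByExpr filter on low counts, robust dispersion and Benjamini-Hochberg adjustment over all genes tested in the comparison at a false discovery rate of 0.05. MCF-7 was fitted alone. The 9 B16 libraries were fitted together with the labelled library type as a covariate. Repeats were fitted in the same way, with library sizes and TMM factors taken from the gene table, so that a shift of all repeats stays visible, and a second time with the repeat table's own sizes and factors. Repeat families with at least 10 tested members were tested with camera. The text names Kdm1a and Ifih1, up to 3 members past the test per fixed list, the 8 highest rises and 8 deepest falls past the test with an absolute log2 fold change of at least 1, an average of at least 2 log2 CPM and groups that do not overlap, and the 5 highest rises and falls among repeats of at least 2 average log2 CPM. Where a gene had no more than 3 counts in a library its fold is left out, and of the unnamed Ensembl identifiers 2 per direction are printed. This rule, the designs, the gene lists and the alternative settings listed in advance were chosen before the data were examined.

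Of 33 mouse gene lists fixed in this way, 26 had enough tested members, and 362 of 505 members were tested. They cover interferon response, antigen presentation, nucleic acid sensing, retroelement silencing, stress, metabolism, melanocyte identity, markers of other cell types and RNAs without a poly-A tail. Lists were tested with camera at an inter-gene correlation of 0.01, then with an estimated correlation and with fry. The names table gave 24210 of 24740 mouse genes and 0 of 60308 human identifiers. The human lists, the comparison of same-symbol genes between the lines and the LSD1 transcript in MCF-7 were therefore not run, and peaks were not assigned to promoters, since no gene coordinates for hg19 or mm9 were at hand.

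Peak lists were compared with bedtools 2.31.1 by overlap of at least 1 bp, and the chance share is the mean over 100 random shifts of the peaks within their chromosomes. Positions are printed counted from 1. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

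Library labels were checked in 2 ways. The median of RNAs without a poly-A tail was compared with the labelled library type, in the gene table and in the repeat table. Repeats and genes were also matched across tables: a repeat that sits in or near a gene follows that gene over the libraries if the 2 tables list the libraries in the same order, so repeats with r above 0.99 to some gene were counted for the labelled order and for 100 random orders. No column was reassigned. Replicate numbers were tested for pairing. In the B16 repeat table all 9 pairs of groups and numbers correlated above 0.1 (0.577 to 0.928), which the shared library type of replicate 3 could give. In 6 of the 9 the same number was the best match both ways. Every pair being over 0.1 was taken as pairing, though this does not tell pairing apart from library type. The repeat values given are from the fit with library type and no block, and the fit with a replicate block is given beside them where it changes the call of a named repeat or moves a count by over 1.5 times. In the gene tables and in MCF-7 they share only a number. No 2 replicates of a group were identical.

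The steps were tested on simulated data. With 200 changed features, edgeR recovered 80.4% of 2-fold and 94.9% of 4-fold changes in MCF-7 genes (5.49% of calls false), 18.6% and 76.5% in B16 genes (3.13%) and 96.0% and 98.0% in B16 repeats (6.8%). DESeq2 1.42.0 recovered 50.5% of 2-fold changes in B16 genes, with 32.8% of its calls false. The peak overlap returned 4 of 4 known answers, and the cross-table match found 50 of 50 made followers in the true order and 0 in a shuffled order.

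Alternatives were other normalizations, no filter on low counts, DESeq2, an added minimum log2 fold change of 1, a replicate block, no library type, libraries labelled rRNA-depleted only, only the 6 libraries compared, own scaling of repeats, leaving out each library in turn, and for peaks a −log10 q-value of at least 5, a reciprocal overlap of 50% and equal numbers of the strongest peaks. Leaving out the 4 gene-table columns that contradict their labelled library type, and the combinations with own scaling, were added after seeing the data. Where leaving out a library left 1 in an arm, it was taken to vary like the others.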

Results

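RNA-seq and ChIP-seq were collected from 2 tumour cell lines in which LSD1, a histone demethylase that removes methyl groups from H3K4me1 and H3K4me2, had been reduced or deleted. MCF-7, a human breast cancer line, was grown in culture with a control short hairpin RNA or with 1 against LSD1, and gave 2 RNA libraries per group. B16, a mouse melanoma line, was grown as tumours in mice for 14 days, and the sorted tumour cells gave 3 RNA libraries from each of 3 groups: scramble guide, LSD1 knockout, and LSD1/MDA5 double knockout. MDA5 (gene Ifih1) is a cytoplasmic sensor of double-stranded RNA that switches on interferon genes. Each RNA library was counted over genes and over named repeat families. ChIP-seq peak lists covered LSD1, H3K4me1 and H3K4me2 in control and LSD1-depleted cells of each line, with 1 library per antibody and arm, so the arms were compared without a test. The series title ties the work to anti-tumour immunity, so the comparisons ask what loss of LSD1 did to genes and repeats, whether loss of MDA5 changed that, and where LSD1 and its substrates lay on the genome.

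Gene counts totalled 16.3M to 20.1M per MCF-7 library and 25.7M to 38.1M per B16 library (M, 1000000 counts). Repeat counts totalled 55.6M to 68.9M and 68.9M to 90.9M. Levels are given as CPM, counts scaled to a library of 1000000. For genes the library size was adjusted by its TMM factor, and for levels of single repeats it was the unadjusted total of repeat counts. Ribosomal RNA repeats took 1.10% to 4.40% of the repeat counts in MCF-7 and 8.85% to 17.6% in B16. Per the labels, replicates 1 and 2 of each B16 group were depleted of ribosomal RNA and replicate 3 was selected for poly-A tails, while every MCF-7 library was depleted of ribosomal RNA.

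LSD1 knockdown changed a large part of the MCF-7 transcriptome. Of 17308 genes tested, 3477 rose and 3315 fell at an edgeR false discovery rate of 0.05 (n = 2 cultures per group), and 1322 rose and 1024 fell by at least a doubling or halving. ENSG00000271601.3 had the highest rise among the genes named by the rule set in advance, from 0.433 and 0.751 to 23.1 and 27.2 CPM, a log2 fold change of 5.44 (SE 0.24, edgeR adjusted p 3.51e-34). ENSG00000121236.19 rose by 4.53 (SE 0.24, edgeR adjusted p 2.78e-29). ENSG00000198691.11 fell from 22.9 and 14.8 to 0.244 and 0.277 CPM, a log2 fold change of −6.16 (SE 0.30, edgeR adjusted p 1.34e-26). ENSG00000215182.6 had a log2 fold change of −5.49 with a wider error (SE 0.94, edgeR adjusted p 0.0378). Its 2 control libraries stood at 23.1 and 9.63 CPM. The genes of this table carry Ensembl identifiers that matched none of the names at hand (0 of 60308), so the LSD1 transcript and the interferon-stimulated genes were not looked up in MCF-7. The count of changed genes was 4446 without LSD1 knockdown replicate 1 and 4404 without replicate 2.

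Few repeats changed in MCF-7. Scaled by the gene counts, 31 of 1251 repeats passed the edgeR test, 17 up and 14 down; 116 had an unadjusted p under 0.05. MamRep564, an interspersed repeat of unknown class, rose from 2592 and 2544 to 6486 and 5588 counts, a log2 fold change of 1.14 (SE 0.14, n = 2 per group, edgeR adjusted p 4.77e-13). HERV30-int, the internal part of an endogenous retrovirus of the ERV1 family, fell from 2180 and 1705 to 957 and 816 counts, a log2 fold change of −1.20 (SE 0.15, edgeR adjusted p 2.67e-13). Transfer RNA repeats had 7 of 52 members up, none down (6 up with repeat scaling) and a median log2 fold change of 0.31; the set test gave an adjusted p of 1.84e-14 at the preset correlation and 0.991 with an estimated correlation. Among the 255 ERV1 repeats tested, 2 rose and 3 fell, and none of the 120 LINE L1 or 41 Alu repeats passed. With repeat scaling 17 ERV1 repeats rose and 14 fell, 4 L1 rose and 4 fell, and 1 Alu rose.

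The other MCF-7 repeats named by the rule were (CCTTG)n at 1.03, HERV1_I-int at 0.83, (GTCTG)n at 0.82 and tRNA-Ala-GCA at 0.81 among the rises, and UCON26 at −1.17, HERV-Fc1-int at −0.92, X5B_LINE at −0.78 and the centromeric satellite ALR/Alpha at −0.77 among the falls (log2 fold changes). Scaling by the repeats' own totals called 88 repeats, 54 up and 34 down. With that scaling tRNA-Ala-GCA and ALR/Alpha no longer passed (edgeR adjusted p 0.200 and 0.0982), while MamRep564, HERV30-int and the other 6 did. The count was 4 without control replicate 1 and 7 without control replicate 2. Without control replicate 1, MamRep564, HERV30-int and UCON26 still passed while the other 7 named repeats did not; without control replicate 2, (GTCTG)n, X5B_LINE and ALR/Alpha did not. With own scaling 5 repeats passed without knockdown replicate 2, MamRep564, HERV30-int and ALR/Alpha among them, while (CCTTG)n, HERV1_I-int, (GTCTG)n, UCON26, HERV-Fc1-int and X5B_LINE lost that call (edgeR adjusted p 0.0818 to 0.207). HERV-Fc1-int also lost it without control replicate 1 (log2 fold change −0.58) or knockdown replicate 1. Under own scaling ALR/Alpha gained the call without knockdown replicate 1 or 2, and tRNA-Ala-GCA without control replicate 1 or 2 or knockdown replicate 1.

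In the B16 gene table, the 2 deleted genes did not follow the group labels. Kdm1a, which encodes LSD1, was at 86.4, 84.9 and 162 CPM in the libraries labelled scramble, 163, 23 and 24.3 in those labelled LSD1 knockout, and 93.0, 153 and 20.8 in those labelled double knockout. Ifih1 was at 25.4, 38.3 and 99.2 in the libraries labelled scramble, 90.8, 195 and 174 in those labelled LSD1 knockout, and 26.2, 90.2 and 158 in those labelled double knockout. A guide-directed deletion can leave a transcript in place, so these levels alone do not place a library. RNAs that lack a poly-A tail gave a further conflict: 20 of them had a median of −0.23, 0.12 and 0.25 log2 CPM in the 3 libraries labelled double knockout and 6.48 to 7.43 in the other 6, while the labels name replicate 3 of each group as the poly-A libraries. By that measure 4 of 9 gene-table columns contradicted their labelled library type (scramble 3, LSD1 knockout 3, double knockout 1 and double knockout 2). In the repeat table of the same samples 0 of 9 did, with 11 small nuclear RNAs at 1.15 to 1.47 log2 CPM in the libraries labelled poly-A and 4.27 to 4.88 in the rest. The gene-table comparisons below keep the deposited labels, and each direction in them holds only as far as those labels do.

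**Figure D1:**
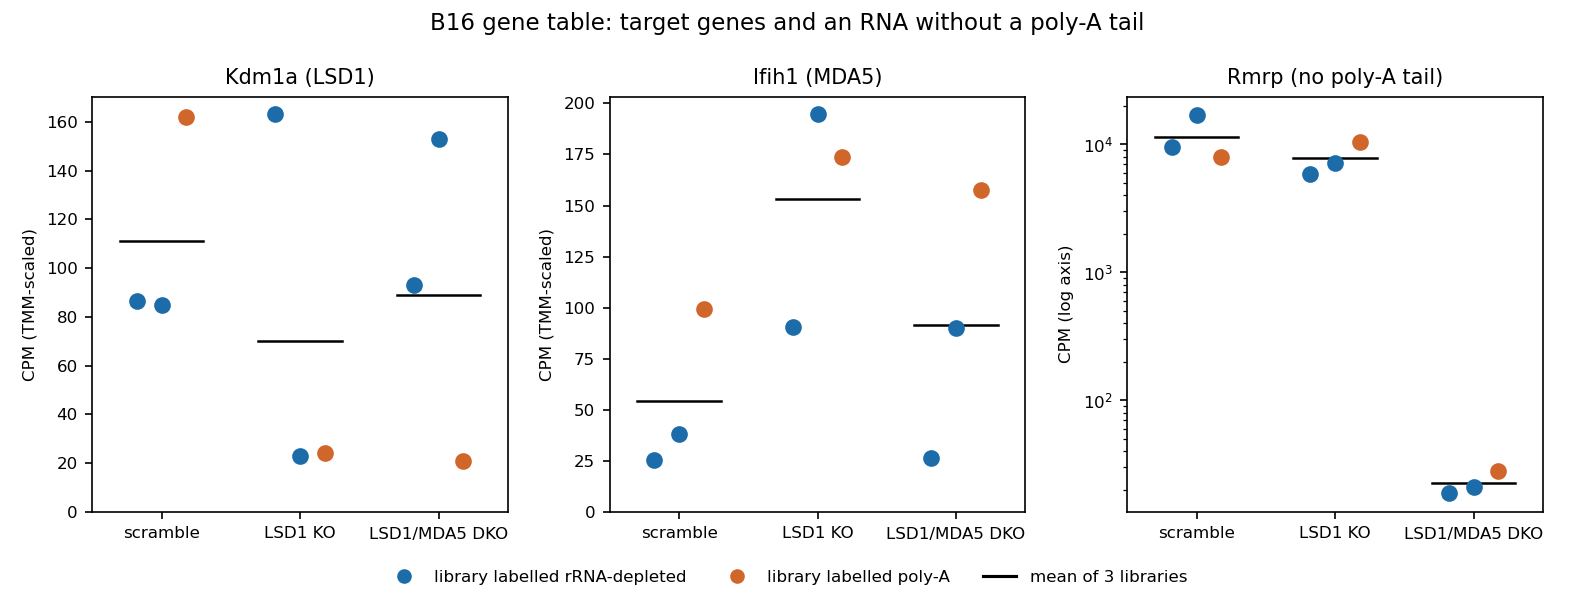
CPM of Kdm1a and Ifih1 (linear axes) and of Rmrp, an RNA without a poly-A tail (log axis), in the 9 columns of the B16 gene table. Columns are placed by labelled group, with points for single libraries, markers by labelled library type and bars for the mean of 3. Kdm1a is at 20.8 to 24.3 in 2 libraries labelled LSD1 knockout and 1 labelled double knockout, and the RNA without a poly-A tail is low in the 3 libraries labelled double knockout.

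Between the libraries labelled LSD1 knockout and scramble, no single gene passed. The edgeR test called 0 of 12882 genes (n = 3 per group), 877 had an unadjusted p under 0.05, and DESeq2 called 25, of which 16 rose and 9 fell. Kdm1a had a log2 fold change of −1.06 (SE 0.94, edgeR adjusted p 0.806), which became 0.23 without the library labelled scramble replicate 3 and −2.23 without LSD1 knockout replicate 1. Ifih1 had a log2 fold change of 1.75 (SE 0.54, edgeR adjusted p 0.727). The labels of these columns are in doubt, as set out above. On simulated data with the same counts and spread, edgeR recovered 18.6% of 2-fold and 76.5% of 4-fold changes. That spread was estimated within the labelled groups, so columns under wrong labels would widen it. Under these labels a doubling of most genes was not detectable, and whether it would be under others was not tested.

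The interferon-stimulated genes, which cells switch on after interferon or double-stranded RNA, were higher as a group in the libraries labelled LSD1 knockout, with 39 of 42 fitted values above 0 and a median log2 fold change of 0.63 (camera adjusted p 0.000549 at the preset correlation of 0.01, 0.853 with an estimated correlation; fry adjusted p 0.795). No member passed by edgeR over all genes or when adjusted over the list alone, and 1 had an unadjusted p under 0.05. Ifit1 stood at 16.5, 30.3 and 91.3 CPM in the libraries labelled scramble and 78.5, 23 and 82.6 in those labelled LSD1 knockout. Stat1 stood at 255, 304 and 1123 against 942, 392 and 1035, so the spread within each labelled group was as wide as the difference between groups.

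MHC class II, which presents antigen to helper T cells, had a median log2 fold change of 1.41 over 7 genes, MHC class I 0.71 over 17, the fibroblast markers 0.80 over 9 and the hypoxia and glycolysis genes 0.24 over 14. The replication-dependent histones were lower, with a median of −0.64 over 16 genes, as were the unfolded protein response genes at −0.52 over 13 and the melanocyte genes at −0.32 over 17. These 7 lists and the interferon list passed camera at the preset correlation, 5 up and 3 down of 26 lists tested. With an estimated correlation 0 of the 26 passed, the estimated adjusted p lying between 0.610 and 0.853 for the 8 lists, and fry called 0. In none of the 26 lists did a member pass by edgeR, either over all genes or adjusted over the list alone. The fibroblast markers were included as a sign of other cells. All 9 had fitted values above 0 in the libraries labelled LSD1 knockout, and 4 had an unadjusted edgeR p under 0.05. Col1a1 stood at 0.335 to 2.42 CPM in the libraries labelled scramble.

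Between the libraries labelled double knockout and scramble, 103 of 12882 genes passed the edgeR test, 7 up and 96 down (n = 3 per group; 726 at an unadjusted p under 0.05), and DESeq2 called 213. In the fixed list of replication-dependent histones, whose messages end in a stem-loop in place of a poly-A tail, 14 of 16 tested members fell past the test, with 16 of 16 adjusted over the list alone and a median log2 fold change of −6.87. Histones outside that list were among the falls too. One of them, Hist1h3f, went from 158, 194 and 139 to 0.431, 0.623 and 0.546 CPM, a log2 fold change of −8.26 (SE 0.25, edgeR adjusted p 6.29e-06). Rpph1, the RNA of ribonuclease P, had a log2 fold change of −10.10 (SE 0.55, edgeR adjusted p 6.43e-05) and Rmrp, the RNA of ribonuclease MRP, one of −9.02 (SE 0.46, edgeR adjusted p 4.73e-05). These directions rest on labels in conflict: the 14 histones and 4 non-coding RNAs of the fixed lists among the falls are of the kind that poly-A selection removes, and all 3 libraries labelled double knockout were low in them although 2 are labelled as depleted of ribosomal RNA.

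Among the genes that rose in the libraries labelled double knockout, Tmem30c went from 0.173, 0.708 and 0.365 to 62.6, 83.0 and 113 CPM, a log2 fold change of 7.68 (SE 0.82, edgeR adjusted p 0.00378). Hmgn5, a nucleosome-binding protein, rose from 9.57, 9.61 and 9.85 to 38.4, 36.4 and 42.2 CPM, a log2 fold change of 2.01 (SE 0.17, edgeR adjusted p 0.00089). Pou4f1, a transcription factor of sensory neurons, had a log2 fold change of 2.33, Hypk one of 1.66 and Pin4 one of 1.17. The libraries labelled double knockout were all low in RNAs without a poly-A tail, and those labelled scramble were not. These rises thus cannot be told apart from an effect of library preparation, which a covariate taken from the labels does not remove. Other named falls were Hist2h2bb at −8.44, Hist1h2bb at −8.35, Scarna10 at −8.20, Hist1h3c at −7.98 and Hist2h3b at −7.77. Pou4f1 no longer passed without the library labelled scramble replicate 2, Hypk without double knockout replicate 1 or 3, and Pin4 whichever of the 6 libraries was left out. The count of changed genes fell to 67 without double knockout replicate 1 and 66 without replicate 3. Kdm1a had a log2 fold change of −0.77 (SE 0.95, edgeR adjusted p 1.00), which became 0.02 without double knockout replicate 3, 0.42 without scramble replicate 3 and −1.35 without scramble replicate 2. Ifih1 had one of 0.79 (SE 0.52, edgeR adjusted p 1.00), which ranged from 0.33 (without double knockout replicate 2) to 1.16 (without replicate 1) leaving out a library.

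Interferon-stimulated genes were higher as a group in the libraries labelled double knockout, with 40 of 42 fitted values above 0 against scramble. The median log2 fold change was 0.63 (camera adjusted p 0.0116, or 0.979 with an estimated correlation). This is not a second, independent observation, since the comparison of LSD1 knockout used the same columns labelled scramble, and those labels are in doubt. No interferon-stimulated gene passed by edgeR over all genes or adjusted over the list alone, and the same was true of the list in every comparison of this table. The unfolded protein response genes had a median of −0.41 (camera adjusted p 0.000668; 0.979 with an estimated correlation), with 0 of 13 past the edgeR test and 1, Trib3, when adjusted over the list alone; of the retroelement silencing genes 0 of 18 passed, and 1, Mphosph8, when adjusted over the list alone. The 4 measured RNAs of the list of non-coding RNAs without a poly-A tail all fell, with a median of −8.34. Of 26 lists, 4 passed camera at the preset correlation, and the histones and the non-coding RNAs without a poly-A tail held with an estimated correlation (adjusted p 0.000248 and 0.00165). The other 22 lists did not pass camera, and fry also called the H3K4 methylation genes, with a median of −0.17 and a fry adjusted p of 0.0267.

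Between the libraries labelled double knockout and LSD1 knockout, 106 genes passed by edgeR, 9 up and 97 down (n = 3 per group). At an unadjusted p under 0.05 there were 872, and DESeq2 called 216. The comparison was planned as the test of what loss of MDA5 added. The 20 RNAs without a poly-A tail had medians of −0.23 to 0.25 log2 CPM in the libraries labelled double knockout. In those labelled LSD1 knockout the medians were 6.48 to 6.75. Loss of MDA5 thus cannot be told apart here from library preparation, and the labels are in doubt. Hist1h3f had a log2 fold change of −8.05 (SE 0.25, edgeR adjusted p 5.94e-06), Rpph1 one of −9.94 (SE 0.55) and Rmrp one of −8.43 (SE 0.45). Tmem30c rose by 6.87 (SE 0.78, edgeR adjusted p 0.00546), Hmgn5 by 1.72 (SE 0.17, edgeR adjusted p 0.00195) and Pou4f1 by 2.22 on the log2 scale. The remaining rises by the rule were Hypk at 1.75, Mrps36 at 1.38, Pin4 at 1.33 and Nsrp1 at 1.11, and the remaining falls Hist2h2bb at −7.83, Hist1h2bb at −7.45, Hist1h3e at −7.43 and Hist1h3c at −7.25. Mrps36 lost the call whichever of the 6 libraries was left out, Nsrp1 in 5 of 6 such fits, Pin4 in 4 and Pou4f1 in 3 (LSD1 knockout replicates 2 and 3 among them for both, with double knockout replicates 2 and 3 for Pin4 and 3 for Pou4f1; for Nsrp1 every library but LSD1 knockout replicate 2). The count was 67 without double knockout replicate 3.

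Ifih1 itself had a log2 fold change of −0.96 between these labelled groups (SE 0.52, edgeR adjusted p 0.741) and Kdm1a one of 0.29 (SE 0.86, edgeR adjusted p 0.959). Ifih1 became −0.42 without LSD1 knockout replicate 2, −0.54 without double knockout replicate 1 and −1.47 without double knockout replicate 2. Kdm1a became 1.80 without LSD1 knockout replicate 1, −0.16 without LSD1 knockout replicate 2, −0.02 without LSD1 knockout replicate 3 and −0.23 without double knockout replicate 2. The interferon-stimulated genes had a median of 0.03, with 24 of 42 fitted values above 0 and a camera adjusted p of 0.909. The melanocyte genes were higher in the libraries labelled double knockout, with a median of 0.32, 16 of 17 fitted values above 0 and a camera adjusted p of 0.00111, but of 0.992 with an estimated correlation. Histones (median −6.58, 14 of 16 past the test and 16 adjusted over the list alone) and non-coding RNAs without a poly-A tail (median −7.88, 4 of 4) were lower and held with an estimated correlation. These 3 of 26 lists passed.

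The LSD1 knockout and double knockout effects share the same 3 scramble columns. Across 12882 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at r = 0.430 and had the same sign in 65.7% of genes. In 20 simulated sets in which neither group differed from scramble, the shared columns alone gave a mean r of 0.503 (SD 0.0147) and the same sign in 66.7%. The covariance was 0.170 against 0.0903 in the simulations, an excess of 0.0792. The simulations drew each gene independently, with the spread estimated within the labelled groups. They thus cover neither correlation between genes nor columns under wrong labels, and the excess cannot be read as a shared effect. No gene passed in both comparisons, against 0 from n1×n2/N. Both values were fixed in advance, since LSD1 knockout against scramble called 0 genes. In the repeat counts, the 4 repeats that fell in LSD1 knockout also fell in double knockout, against 2.76 from n1×n2/N, under a scaling that called 751 of 1089 repeats lower in double knockout. The overlap may thus come from that shift or from the shared controls. There r was 0.611 against a simulated mean of 0.536 (SD 0.109), and the sign was the same in 39.3% of repeats against a simulated 66.9%.

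In the B16 repeat table, LTR52-int, the internal part of an ERVL retrovirus, was far lower in the libraries labelled LSD1 knockout. It had 1462, 1351 and 540 counts in the libraries labelled scramble and 79.5, 77.5 and 38.0 in those labelled LSD1 knockout, a log2 fold change of −4.03 (SE 0.31, n = 3 per group, edgeR adjusted p 0.000241). With the repeats' own scaling the log2 fold change of LTR52-int was −4.06 (edgeR adjusted p 0.00252). It passed without each of the 6 libraries in turn under the gene-table scaling. With own scaling the adjusted p was 0.0540 without LSD1 knockout replicate 1 and 0.0507 without replicate 2, while the log2 fold change stayed between −4.31 and −3.96 whichever library was left out. RLTR46, a long terminal repeat of the ERVK family, rose by 1.12 (SE 0.18, edgeR adjusted p 0.0309). Of the intracisternal A-particle elements, IAPEy-int had a log2 fold change of −0.82 (edgeR adjusted p 0.0375) and IAPEz-int one of −0.51 (SE 0.09, edgeR adjusted p 0.0375, or 0.0561 with own scaling), while IAPLTR4 had one of 1.04 (edgeR adjusted p 0.0547), or 1.01 with own scaling (edgeR adjusted p 0.0203). IAPEz-int stood at 7419, 7830 and 8466 CPM of the repeat table in the libraries labelled scramble and 5500, 5971 and 5753 in those labelled LSD1 knockout.

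Of 1089 repeats, 5 passed by edgeR with the gene-table scaling, 1 up and 4 down (80 at an unadjusted p under 0.05; the fifth, MER49, at −0.88, was named after its values were seen), while 36 passed with the repeats' own scaling, 20 up and 16 down. The gene-table scaling rests on columns whose labels are in doubt. With a replicate block 8 passed with the gene-table scaling and 13 with own scaling. More passed with DESeq2 or when only the 6 libraries compared were fitted, as given below. RLTR46, IAPEy-int and IAPEz-int each lost the gene-table-scaled call when any of the 6 libraries was left out, at log2 fold changes of 1.05 to 1.23, −0.90 to −0.78 and −0.54 to −0.48, which left 1 to 3 repeats past the test. With own scaling as well, leaving out a library left few calls: 0 without LSD1 knockout replicate 1 or 2, 1 without LSD1 knockout replicate 3 or scramble replicate 1, 2 without scramble replicate 3 and 6 without scramble replicate 2. MER73, an ERVL repeat, stood at 3.43, 3.82 and 3.25 CPM of the repeat table in the libraries labelled scramble and 21.1, 19 and 19.2 in those labelled LSD1 knockout; it passed with own scaling at a log2 fold change of 2.41 (SE 0.46, edgeR adjusted p 0.0446) and not with the gene-table scaling (edgeR adjusted p 0.242). IAPLTR4 (1.01), MamRep38 (0.93), MER97b (0.65), L1ME5 (−0.41), RLTR13B3 (−0.43) and MER34B-int (−0.33) also passed with own scaling and not with the gene-table scaling. With the replicate block, IAPLTR4 and MamRep38 passed with the gene-table scaling (edgeR adjusted p 0.0304 and 0.0353), and with own scaling L1ME5 still passed while MER73, IAPLTR4, MamRep38, MER97b, RLTR13B3 and MER34B-int did not (edgeR adjusted p 0.0502 to 0.0730). These 7 each lost the own-scaled call whichever of the 6 libraries was left out, RLTR46 for each but scramble replicate 2, and IAPEy-int for each but scramble replicates 2 and 3. The ERVK family had 1 member up and 2 down of 147, or 7 up and 4 down with own scaling.

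**Figure D2:**
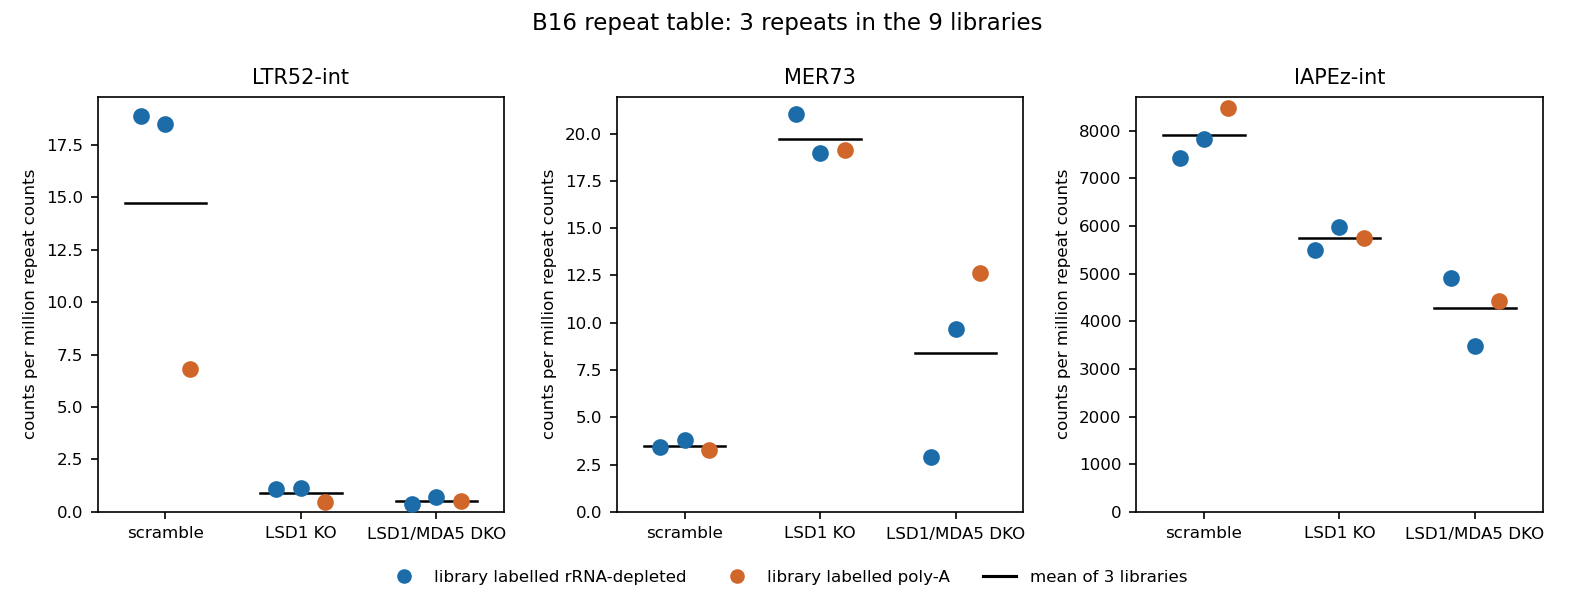
CPM of LTR52-int, MER73 and IAPEz-int over repeat counts in the 9 columns of the B16 repeat table by labelled group, with points for single libraries, markers by labelled library type and bars for the mean of 3. LTR52-int is under 1.2 in each of the 6 libraries labelled LSD1 knockout or double knockout and at 6.82 to 18.9 in those labelled scramble.

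LTR52-int was also low in the libraries labelled double knockout, with 32.0, 63.0 and 38.5 counts and a log2 fold change against scramble of −4.82 (SE 0.33, n = 3 per group, edgeR adjusted p 7.61e-05), or −4.38 with own scaling (edgeR adjusted p 0.00205). The gene-table scaling placed the whole repeat table lower in these libraries, by a median of −0.45 log2 against scramble and −0.48 against LSD1 knockout. Against scramble it called 754 of 1089 repeats by edgeR, 3 up and 751 down. With own scaling, which sets that median near 0, 36 passed, 13 up and 23 down, or 14 with a replicate block as well. Nearly all of the 754 calls were also lost with the libraries labelled rRNA-depleted only, as given below. IAPEz-int had a log2 fold change of −1.03 with the gene-table scaling (edgeR adjusted p 7.7e-05) and −0.55 with own scaling (edgeR adjusted p 0.0565). Of 147 ERVK repeats 121 fell with the gene-table scaling, and 3 rose and 7 fell with own scaling. The gene totals behind the first scaling come from the table in which 4 columns contradict their labelled library type.

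Other repeats named against scramble were U8 at 1.15, (TTTC)n at 0.61 and MamRep38 at 0.48 among the rises, and RLTR44D at −1.04, (TATAA)n at −1.02 and IAPEY_LTR at −1.02 among the falls; with own scaling (TTTC)n (1.07) and MamRep38 (0.93) passed and U8, RLTR44D, (TATAA)n and IAPEY_LTR did not. With own scaling and a replicate block (TTTC)n and MamRep38 did not pass either (edgeR adjusted p 0.0809 and 0.0534). With the gene-table scaling, (TTTC)n lost the call without double knockout replicate 1 or whichever scramble replicate was dropped, and MamRep38 without double knockout replicate 2 or 3 or whichever scramble replicate was dropped. U8 lost it without scramble replicate 1, (TATAA)n without scramble replicate 1 or 2, and RLTR44D without scramble replicate 3. Own scaling also called falls of ERVL-B4-int (−0.51), IAPEy-int (−0.51), MER34B-int (−0.43) and LTR16D2 (−0.54), and rises of RLTR46 (0.74), MT-int (0.49) and MLT1G3-int (0.49). With a replicate block as well, ERVL-B4-int, MER34B-int, RLTR46 and MT-int passed, and IAPEy-int, LTR16D2 and MLT1G3-int did not (edgeR adjusted p 0.0534, 0.0710 and 0.0597). The own-scaled calls of (TTTC)n, MamRep38 and these 7 were lost without scramble replicate 1 or 3, and all but that of ERVL-B4-int without scramble replicate 2; LTR16D2, IAPEy-int and RLTR46 also lost theirs without double knockout replicate 2 or 3, (TTTC)n without 1 or 2, and MamRep38, MT-int and MLT1G3-int without 3. IAPEz-int and IAPEY_LTR gained the own-scaled call without double knockout replicate 1, and U8 without replicate 2, while LTR52-int passed without each library. Leaving out a library under own scaling left 1 or 2 repeats whichever scramble replicate was dropped, 10 without double knockout replicate 3, and 207 without double knockout replicate 1.

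Between the double knockout and LSD1 knockout libraries of the repeat table, MuRRS4-int, an ERV1 retrovirus, was higher, with 142365, 136879 and 64794 counts against 38079, 39140 and 57382, a log2 fold change of 1.00 (SE 0.29, n = 3 per group, edgeR adjusted p 0.0166), or 1.50 with own scaling (edgeR adjusted p 0.0431). It lost the gene-table-scaled call without LSD1 knockout replicate 1 or double knockout replicate 1 or 2. MER97b, a DNA transposon, was lower at −1.31 (own scaling −0.82, edgeR adjusted p 0.0237), and IAPLTR4 at −1.21 (own scaling −0.73, edgeR adjusted p 0.0431). In all, 797 repeats passed by edgeR with the gene-table scaling, 12 up and 785 down. With own scaling 63 passed, 29 up and 34 down, or 21 with own scaling and a replicate block. The gene-table scaling rests on columns whose labels are in doubt, as set out above. The other named repeats were Lx3_Mus at 1.17, U4 at 0.98, U8 at 0.91, L1MD at 0.82, RLTR44D at −1.68, MER73 at −1.30 and RMER6D at −1.23, of which U4 alone also passed with own scaling. With a replicate block Lx3_Mus, U8, L1MD and MER73 lost the gene-table-scaled call (edgeR adjusted p 0.0727 to 0.0826), and MuRRS4-int, U4 and IAPLTR4 the own-scaled one (edgeR adjusted p 0.0724 to 0.0828). The own-scaled calls of MuRRS4-int, U4, MER97b and IAPLTR4 were also lost without LSD1 knockout replicate 1 or 2, those of MuRRS4-int and U4 without double knockout replicate 1 or 2, and that of IAPLTR4 without LSD1 knockout replicate 3 or double knockout replicate 2 or 3. RLTR44D, RMER6D and MER73 gained that call without double knockout replicate 1, U8 without 2, L1MD and Lx3_Mus without 3, and L1MD also without LSD1 knockout replicate 3. Lx3_Mus, U4, U8 and L1MD lost the gene-table-scaled call without LSD1 knockout replicate 1 or 2 or double knockout replicate 1, U4 and L1MD also without double knockout replicate 2, and MER73 for each library left out but double knockout replicate 1. Under own scaling 2 repeats passed without LSD1 knockout replicate 1 or 2, 16 without replicate 3, 21 without double knockout replicate 3, and 214 without double knockout replicate 1. MER73 stood at 2.88, 9.69 and 12.6 CPM of the repeat table in the libraries labelled double knockout.

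The same repeat names could be compared between the lines. Of 706 repeats tested in each, 12 passed in MCF-7 knockdown and 2 in B16 LSD1 knockout by edgeR with the gene-table scaling, and 0 in both. With so few calls, unrelated lists would give 0 as well, so this does not show whether the lines differ. LTR52-int had a log2 fold change of 0.02 in MCF-7, where it did not pass.

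In MCF-7, LSD1 peaks nearly disappeared after knockdown, from 2355 in the control to 24. Of the 2355 control peaks 7 (0.297%) were found again by at least 1 bp, and 7 of the 24 knockdown peaks (29.2%) lay on control peaks, against 0.0417% for peaks placed at random. The control peak of highest fold was on chromosome 9 at 127534001 to 127534391 (hg19), with 16.5 by the authors' fold enrichment. The next, on chromosome 1 at 170064114 to 170064730 with a fold of 15.7, was found in the knockdown too. In the knockdown list the highest fold, 21.2, was on chromosome 3 at 138328192 to 138328601, on a control peak. H3K4me2, a mark of promoters and enhancers, lay under 61.3% of control LSD1 peaks (2.97% by chance), and H3K4me1, a mark of enhancers, under 8.49%.

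The number of H3K4me1 peaks in MCF-7 went from 7117 to 34291 after knockdown and their covered length from 2.74 to 15.2 Mb, while H3K4me2 went from 67693 to 76861 peaks and from 59.0 to 66.7 Mb. Of control H3K4me1 peaks 56.0% were found again, and 11.4% of knockdown peaks lay on control peaks. For H3K4me2 these shares were 82.1% and 72.1%. H3K4me1 peaks seen only after knockdown lay on control H3K4me2 in 42.1% of 30395 cases, against 84.0% of those on a control H3K4me1 peak and 2.92% by chance. The control LSD1 peaks carried H3K4me1 in 8.49% of cases before and 22.3% after knockdown, against 0.220% and 0.983% by chance. Median fold enrichment was 4.40 and 4.11 for H3K4me1 in control and knockdown; fold and score are the authors' own, computed per library.

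In B16 tumour cells, LSD1 peaks went from 7157 in the scramble library to 427 in the LSD1 knockout. Of these 427, 403 (94.4%) lay on scramble peaks against 0.145% by chance, and 5.57% of the scramble peaks were found again. H3K4me2 lay under 94.6% of the LSD1 peaks left in the knockout and under 51.0% of those in scramble. The scramble peaks of highest fold, at mm9 positions, were on chromosome 16 at 76866169 to 76866621 (fold 54.3, found in the knockout too), chromosome 15 at 72398784 to 72399444 (fold 53.9, not found in the knockout) and chromosome 1 at 173192917 to 173193426 (fold 51.0). In the knockout the highest was on chromosome 1 at 173193057 to 173193408, with a fold of 33.7, and each of its 5 strongest peaks lay on a scramble LSD1 peak and on H3K4me2.

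For the histone marks, the ratio of peak numbers was nearer to 1 in B16 than in MCF-7, a difference that was not tested. H3K4me1 went from 126561 to 140732 peaks and from 73.2 to 92.1 Mb, and H3K4me2 from 124026 to 129624 peaks and from 109 to 119 Mb. Of scramble peaks 71.6% of H3K4me1 and 81.3% of H3K4me2 were found again in the knockout, and 60.3% and 74.0% of knockout peaks lay on scramble peaks. H3K4me1 peaks seen only in the knockout lay on scramble H3K4me2 in 33.5% of 55807 cases, against 85.5% of those shared. The scramble LSD1 peaks carried H3K4me1 in 27.9% of cases in scramble and 31.4% in the knockout. The chance share rose too, from 4.18% to 5.02%, so these shares do not show a gain at LSD1 sites.

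**Figure D3:**
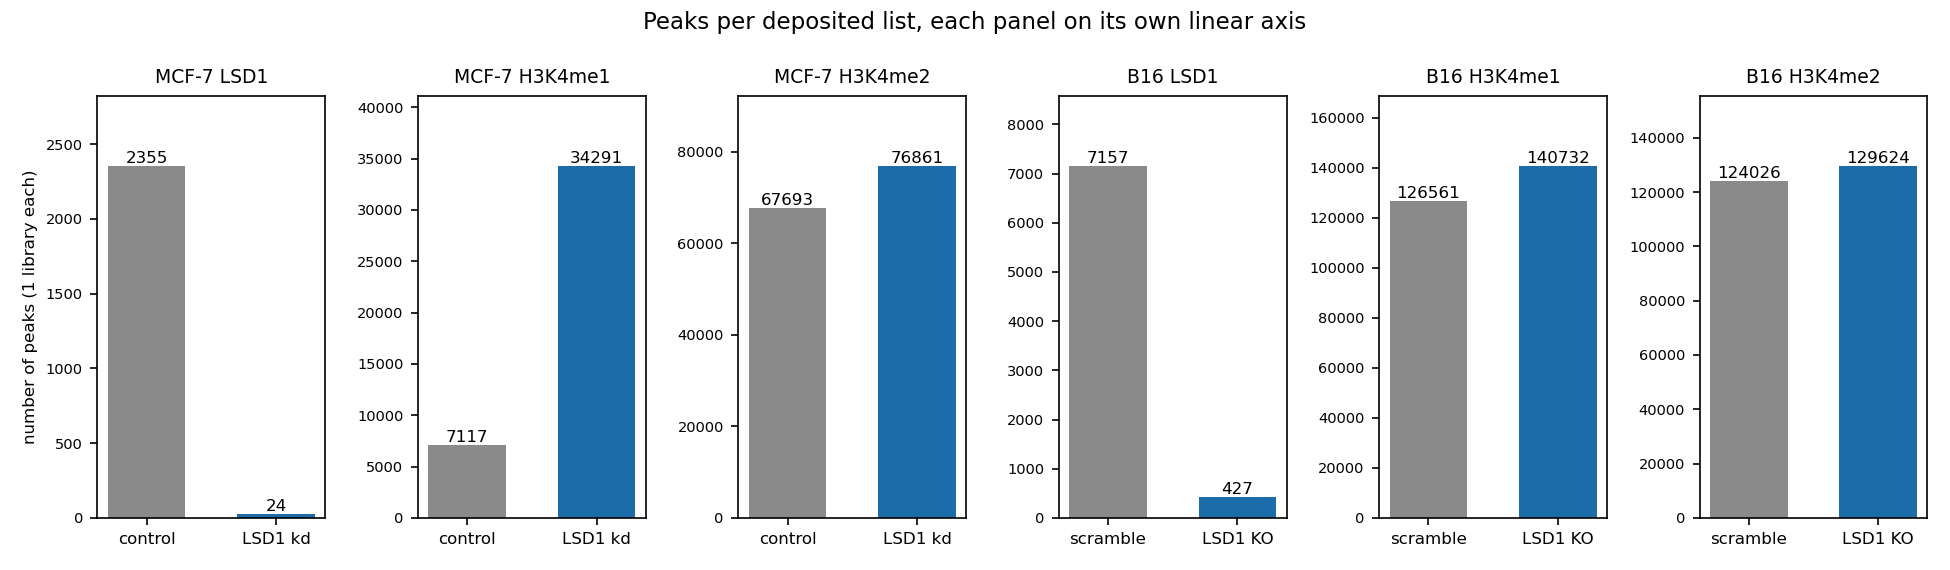
Number of peaks in each deposited list (linear axis, 1 library per bar) for LSD1, H3K4me1 and H3K4me2 in MCF-7 control and knockdown cells and in B16 scramble and LSD1 knockout tumour cells. LSD1 peaks drop from 2355 to 24 in MCF-7 and from 7157 to 427 in B16, and MCF-7 H3K4me1 goes from 7117 to 34291.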

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

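The settings with own scaling combined with another choice, and the one that leaves out the 4 gene-table columns contradicting their library type, were chosen after seeing the data; the rest were planned. In the 2 comparisons of the double knockout, leaving out these columns keeps 1 double knockout library, the only one left that is labelled poly-A, so library type is confounded with group and those values say nothing about the results. Where a value moved, the cause was not tested unless stated.

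MCF-7 genes numbered 6792 and stayed within 1.5 times of that with RLE (6816), upper quartile (6714), no filter (6698), DESeq2 (4777, 4768 shared) and the replicate block (6060, 6017 shared). With a log2 minimum of 1 there were 2346, and leaving out a library gave 4404 to 6599. MCF-7 repeats numbered 31, with own scaling 88, own scaling and DESeq2 87, own scaling and the replicate block 138, the replicate block alone 7 and a log2 minimum of 1, 4; leaving out a library gave 4 to 38, and 5 to 116 with own scaling. Replicate numbers did not pair the MCF-7 libraries.

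B16 genes labelled LSD1 knockout against scramble numbered 0 by edgeR under 15 of 16 settings (877 at an unadjusted p under 0.05) and 25 with DESeq2; leaving out a library gave 0. Double knockout against scramble had 103 genes, 213 with DESeq2, 62 with rRNA-depleted libraries only, 33 without the 4 doubtful columns and 66 to 81 leaving out a library. Double knockout against LSD1 knockout had 106, then 216, 64, 18 (0 up) and 67 to 99. Interferon-stimulated genes past the edgeR test were 0 in all 16 settings of each comparison. Fixed lists went from 8 to 0 with an estimated correlation and 0 with fry for LSD1 knockout, and from 4 to 2 with an estimated correlation for double knockout against scramble; the 3 of the last comparison became 2 under each.

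B16 repeats for LSD1 knockout against scramble numbered 5. Other values were 36 with own scaling, 14 with DESeq2, 120 with both, 2 with a log2 minimum of 1, 8 with the replicate block (13 with own scaling), 1 without library type (2), 1 with rRNA-depleted libraries only (1) and 170 with only the 6 libraries compared; leaving out a library gave 1 to 3, and 0 to 6 with own scaling. For double knockout against scramble the 754 became 36 with own scaling, 135 with own scaling and DESeq2, 20 with a log2 minimum of 1, 14 with own scaling and the replicate block, 367 without library type (2 with own scaling) and 2 with rRNA-depleted libraries only (7); leaving out a library gave 504 to 849, and 1 to 207 with own scaling. For double knockout against LSD1 knockout the 797 became 63, 179, 28, 21, 513 (0) and 512 (7) in the same order, 579 to 879 leaving out a library, and 2 to 214 with own scaling. In the 2 comparisons of the double knockout own scaling, which removes the shift of the whole table, ended most of the calls. Against scramble the rRNA-depleted libraries alone, without own scaling, ended most of them too.

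The correlation of the LSD1 knockout and double knockout effects was 0.430, 0.317 over the 103 genes past the test in either, and 0.277 to 0.598 leaving out a library.

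Kdm1a changed sign between settings. For LSD1 knockout against scramble it was −1.06, and 0.12 with rRNA-depleted libraries only, 0.12 without the doubtful columns and −2.23 to 0.23 leaving out a library. For double knockout against scramble it was −0.77, 0.52 with rRNA-depleted libraries only, −2.04 without the doubtful columns and −1.35 to 0.42 leaving out a library, and Ifih1 went from 0.79 to 2.31 without the doubtful columns and 0.33 to 1.16 leaving out a library. For double knockout against LSD1 knockout it was 0.29, −2.16 without the doubtful columns and −0.23 to 1.80 leaving out a library, and Ifih1 went from −0.96 to 0.15 without the doubtful columns and −1.47 to −0.42 leaving out a library. None of these passed the test. Of 1322 values of the 94 single genes and repeats over all settings, 1039 kept direction and side of the threshold, 244 kept direction and lost the call, 28 gained it and 11 changed sign.

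Among peaks, the ratio of numbers between arms kept its direction at a −log10 q-value of at least 5 for each antibody and line (LSD1 0.0150 and 0.0754, H3K4me1 7.20 and 1.34, H3K4me2 1.15 and 1.05). Overlap shares moved, in order for that threshold, a reciprocal overlap of 50% and equal numbers: MCF-7 H3K4me1 control peaks 53.6%, 23.1% and 16.2%, knockdown peaks 7.16%, 4.79% and 14.8%; H3K4me2 84.4%, 62.1% and 77.6%, then 74.5%, 54.7% and 76.1%. For B16 these were LSD1 scramble 7.11%, 4.35% and 46.4%; H3K4me1 68.9%, 32.0% and 67.4%, then 49.7%, 28.8% and 61.5%; H3K4me2 84.9%, 56.2% and 79.9%, then 77.4%, 53.8% and 75.3%. LSD1 knockout peaks went to 72.8% at reciprocal overlap and 46.6% at equal numbers, and each MCF-7 LSD1 share to 8.33% at equal numbers. Reciprocal overlap is stricter by construction.

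Peaks at promoters, within 2 or 5 kb, and the MCF-7 lists were not run. The B16 gene table was deeper than that of MCF-7 (25.7M counts or more per library against 20.1M or less). Its biological coefficient of variation, estimated within the labelled groups, was 0.300 against 0.0926. At that spread edgeR recovered 18.6% against 80.4% of simulated 2-fold changes.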

Other observations

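All tests in this part were chosen after the results they address had been seen.

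In the B16 gene table, RNAs without a poly-A tail were low in the 3 columns labelled double knockout, and the conflict with the labelled library types may come from columns that stand under other samples' names. Repeats that follow a gene closely should match best when both tables list the libraries in the same order. The labelled order matched 10 of 919 repeats. Of 100 random orders 5 matched at least as many, with a median of 0 and up to 82. A random order seldom meets any 1 true order, so this count could not have borne out another order. The labelled order was not the best matched of those tried, so another order is not excluded. Of 100 random orders that pair low with low poly-A-lacking RNA 91 matched at least as many, but those orders align the columns that differ most, which by itself raises the matches. Against a general loss of such RNAs through the double knockout itself stand the 11 small nuclear RNAs of the repeat table. Among rRNA-depleted libraries they were 0.30 log2 higher in the double knockout than in scramble. The gene table gave −7.39 for 20 other RNAs, so a loss of those alone is not excluded by this. Against wrong library types with right groups, 0 of 9 repeat-table columns contradicted the labelled type. By Kdm1a and Ifih1 levels the gene-table columns fell into 3 sets that cross the labelled groups. Scramble 1 and 2 went with double knockout 1, and scramble 3 and LSD1 knockout 1 with double knockout 2. LSD1 knockout 2 and 3 went with double knockout 3. The nearest column by rank correlation over genes lay in the same set for each of the 9 columns. Each set held 1 of the 3 columns low in RNAs without a poly-A tail and 2 that were not. That is the make-up of library types that the labels give each group. These values argue against the labelled groups in the gene table, and for columns that stand under other samples' names. Which sample each column belongs to stays open, so that the gene-table directions of this line rest on labels that the tables do not bear out.

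LTR52-int was low in the libraries labelled LSD1 knockout of the B16 repeat table. The scaling by the gene table was not the cause, since own scaling left a log2 fold change of −4.06, and −4.31 to −3.96 leaving out a library (edgeR adjusted p up to 0.0540, without LSD1 knockout replicate 1). Nor was library type, since the weaker of the ratios within each type was −3.79. The libraries labelled double knockout had −4.38 with own scaling. If the repeat-table labels hold, loss of LSD1 may lower LTR52-int in these tumour cells; Kdm1a did not follow the labels in the gene table. A repeat of this low count could be transcribed from a few sites, and a difference between the cell clones or a deletion at such a site was not tested.

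More H3K4me1 peaks were called in MCF-7 after LSD1 knockdown. A deeper or better enriched knockdown library was taken to find at least 80% of control peaks again and to add weaker ones. That cutoff was set after the data were seen and was not calibrated. Of control peaks 56.0% were found again, peaks of the knockdown alone had a median fold of 4.10 against 4.15 for those on control peaks, and control peaks not found again had 4.46 against 4.33 for those found. None of these is what was set for more depth alone, but a control library with many false peaks could give them too. Of the control peaks 21.4% reached a −log10 q-value of 5. With 1 library per arm, no spread and no depth, better enrichment and a true gain cannot be told apart. The share of the sites LSD1 had occupied that carried H3K4me1 went from 8.49% to 22.3%, 2.63 times as high, against 0.220% and 0.983% by chance. The ratio was to be compared with the 4.82 times as many peaks, but a share that starts so far above chance holds the ratio down, so that comparison shows nothing for or against a gain at LSD1 sites. Whether the gain lay there stays open.

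Other splits of the 6 libraries of each B16 comparison number 10 with the real one, too few for a share under 0.05. For LSD1 knockout against scramble the real split called 0 genes (highest other split 0; 10 of 10 splits as large), 5 repeats (2; 1 of 10), 8 lists (10; 3 of 10) and 0 interferon-stimulated genes (0; 10 of 10). For double knockout against scramble it called 103 genes (619; 2 of 10), 754 repeats (18; 1 of 10), 4 lists (13; 10 of 10) and 0 interferon-stimulated genes (13; 10 of 10). For double knockout against LSD1 knockout it called 106 genes (1885; 3 of 10), 797 repeats (14; 1 of 10), 3 lists (11; 10 of 10) and 0 interferon-stimulated genes (8; 10 of 10). In the gene table, splits that call several times the real number point to a structure of the samples other than the labelled groups. In the repeat table the replicate numbers were taken to pair the libraries, which the shared library type of replicate 3 could also give. There the 3 other splits that part each number called at most 0, 2 and 7 repeats in the same order of comparisons. The remaining splits put 2 libraries of 1 number on the same side. All splits used the gene-table scaling, which placed the whole repeat table lower in the libraries labelled double knockout. Only the real split parts all of those from the rest, so the 754 and 797 calls show nothing for the labelled groups. With own scaling they were 36 and 63, and no other split was run.

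The split with 619 genes set double knockout replicate 1 and scramble replicates 1 and 2 against the rest. That with 1885 genes set LSD1 knockout replicate 1 and double knockout replicates 1 and 2 against the rest. Each of these splits put 1 of the 3 sets of gene-table columns described above on a side of its own. The nearest library by rank correlation was of the same labelled group for 3 of 9 columns in the gene table and 5 of 9 in the repeat table.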
